A study of Homo sapiens with 6 samples.

How the data were processed

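Poly(A)-selected RNA of HCT116 cells was sequenced in 6 libraries, 3 labelled MLL4 wild type (MLL4WT) and 3 labelled MLL4 knockout (MLL4KO), with the genotype and the replicate number taken from the sample labels. Total RNA was taken up with a column kit and made into libraries with a kit that the labels do not say keeps strand, per the labels' protocols. The deposited values are expected counts, estimated per gene and given as whole numbers for 59715 Ensembl gene IDs, with no normalisation, per the file headers and the values themselves. Salmon 1.8.0, DESeq2 1.44.0 and the hg38 build are named in the submitters' processing notes with no role or order, so the tool that made the estimates is not stated. The annotation release behind the gene IDs is not given in the sources used here. Counts of genes with near-identical copies or overlapping exons depend on how the authors' counting shared reads, which these values cannot show.

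Every ID named a gene, and all 6 columns of the table were used. Of the 59715 IDs, 27126 had at least 1 count. Symbols came from a table of gene names that held 55764 of the IDs and 26450 of the counted ones, and 0.186% of counts fell in IDs without a symbol there. Coordinates and gene types came from GENCODE release 29 on GRCh38, which held 56227 of the IDs; GRCh38 is the build that the processing notes call hg38.

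Library totals ranged from 6829400 to 19736751 counts. The shallowest library, MLL4WT replicate 1, holds 3 counts, the floor used for a count of 0, at 0.439 CPM, so differences in genes near or under that level were not detectable at this depth in that library. Counts were not rounded, being whole already. Genes were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 14543 genes with 99.9% of the counts, 833 of them with no symbol. Libraries were scaled by TMM, and MLL4KO was compared with MLL4WT by the edgeR quasi-likelihood test with robust dispersion estimates, no covariate and 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes with an adjusted p under 0.05 are said to have risen or fallen. The biological coefficient of variation was 5.62%. CPM values used the same scaling. Standard errors of log2 fold changes were computed from the quasi-likelihood F statistic. Genes with 0 counts in a group got a lower bound on the fold at a floor of 3 counts over the group, and genes with 1 to 3 counts an exact 95% counting interval of the ratio.

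Before the data were examined, 23 gene lists with 696 memberships of 687 different genes were fixed, 1 member was matched through an older symbol, and PAGR1 was not matched to an ID. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 23 lists, with the correlation estimated from the data, camera on ranks and fry as alternatives. The genes named in the text were also set by a rule fixed then: KMT2D, KMT2B and KMT2C, the 10 largest rises and 10 largest falls among called genes with a symbol, at least 5 CPM in the higher group and no overlap between the groups, and for each list the called members with the smallest adjusted p, at most 2 that rose and 2 that fell, or 4 of each plus CDKN1A and MDM2 for the p53 targets. Genes named outside that rule are KDM6A and RUNX1 and those of the closing section, chosen after their values were seen. Some genes that the rule names are not reported here.

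Alternatives fixed before the data were examined were size factors of the DESeq2 kind, total counts and upper quartile factors, no filter and a stricter filter, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, and leaving out each library. Those added later were a flow cell term from codes in the column names, thinning to the shallowest library, removal of GC and length trends per library by lowess with a span of 0.3, and leaving out chromosome 21 and a segment of chromosome 8. Windows of 100 neighbouring tested genes and segments of at least 30 genes were scanned along each chromosome, with 100 shuffles of gene order.

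The gene test was checked on simulated counts drawn from the real means, totals and dispersions of the 14543 genes, with 50 genes changed at each fold size in each of 5 draws. It recovered 46.4% of genes changed 1.25-fold, 64.8% at 1.5-fold, 83.6% at 2-fold and 90.4% at 4-fold. Of 778 calls over the draws, 65 (8.36%) were of unchanged genes, above the 5% aimed at. The same 200 genes changed in every draw, while 6021 genes were called in the data. The adjusted p threshold then falls at another unadjusted p, so these shares do not carry over to the real test. The list test found the 1 raised list of 20 and no other, and the segment scan found 117 of 120 genes of a lowered segment with 2 others. Simulated genes were drawn independently, so this does not show how the list test behaves where members are correlated.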

Results

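RNA was sequenced from HCT116, an established human colorectal carcinoma line that retains functional p53, in 3 libraries of cells with the histone methyltransferase MLL4 intact (MLL4WT) and 3 of cells in which it was knocked out (MLL4KO). The deposited table gave estimated counts for 59715 genes, of which 14543 had enough counts to be tested. Library totals were 6829400, 15013035 and 17828774 counts in MLL4WT replicates 1 to 3 and 19736751, 15859813 and 14775580 in MLL4KO replicates 1 to 3. The first principal component held 68.2% of the variance and separated the genotypes, and the second held 15.9% and set the shallowest library, MLL4WT replicate 1, apart from the other 5. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of 7.49 and 7.36 for the pairs of MLL4WT replicate 1 with replicates 2 and 3 and between 1.85 and 2.46 for the other pairs of one genotype, and each library was treated as 1 replicate. The labels do not say whether the 3 libraries of a genotype came from separate cultures or clones, and the p-values therefore measure the spread between these samples. Levels are CPM (counts scaled by library size) as mean ± SD over n = 3 libraries, fold changes are MLL4KO relative to MLL4WT, and log2 fold changes carry their standard error. Coordinates are on GRCh38 with GENCODE release 29.

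The comparison asked how transcripts differ once MLL4 is lost, and the targeted gene was examined first. KMT2D, the gene usually meant by MLL4 in human cells (chromosome 12, 49018975 to 49059774), was measured at 240, 231 and 234 CPM in the 3 MLL4WT libraries and 230, 243 and 225 CPM in the 3 MLL4KO libraries, a log2 fold change of -0.01 ± 0.05 (edgeR adjusted p = 0.832). KMT2B, a related methyltransferase gene that has also been called MLL4 (chromosome 19, 35718019 to 35738878), fell 1.42-fold, from 90.5 ± 3.44 to 63.2 ± 3.45 CPM (edgeR adjusted p = 2.33e-05). KMT2C, the close relative of KMT2D, was at 39.4 ± 2.51 CPM in MLL4WT and 39.0 ± 3.31 CPM in MLL4KO (edgeR adjusted p = 0.832). The place of the deletion is not given in the sources used here, and a count over the whole gene does not show a small deletion, so the RNA of these genes does not check the labels.

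Among the subunits of the H3K4 methyltransferase complexes and their partners, 5 of 23 measured genes rose, 4 fell and 14 did not pass the test, with the same 5 and 4 when adjusted over the list alone. PSIP1, a chromatin-bound coactivator, rose 1.32-fold (edgeR adjusted p = 3.40e-05). CXXC1, a CpG-binding subunit of the SETD1 complexes, fell 1.16-fold (edgeR adjusted p = 0.00692), a call lost with GC and length trends removed (log2 -0.09, adjusted p = 0.228) and without MLL4KO replicate 2 (log2 -0.17, adjusted p = 0.0589). The median log2 fold change of the list was 0.01, and camera did not set it apart from the other genes (adjusted p = 0.815). With total counts alone 6 members rose and 2 fell, and without MLL4KO replicate 2 it was 3 and 1.

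Across the transcriptome the largest falls reached near-complete loss of single transcripts, while rises were smaller. CYP24A1, which encodes the enzyme that inactivates vitamin D (chromosome 20, 54153449 to 54173973), fell 73.8-fold, from 420 ± 30.6 to 5.74 ± 0.534 CPM (log2 -6.21 ± 0.08, edgeR adjusted p = 3.48e-13). LRP12, a membrane receptor gene, had 611 counts over the MLL4WT libraries and 0 over the MLL4KO libraries, at least 270-fold lower at a floor of 3 counts over the group. MAGEB1, a cancer-testis antigen gene on chromosome X, went from 215 to 0 counts, at least 95.1-fold lower by the same floor. PKIA, an inhibitor of cAMP-dependent protein kinase, went from 344 to 2 counts (ratio 228, 95% counting interval 62.7 to 1892), and PRICKLE2, a planar cell polarity gene, from 426 to 3 counts (ratio 188, interval 64.0 to 917). These floors and intervals cover counting error only.

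The other 5 of the 10 largest falls among genes at 5 CPM or more in the higher group were the long noncoding RNA SFTA1P (543 counts over the MLL4WT libraries and 6 over the MLL4KO libraries), the type IV collagen chain gene COL4A5 (654 and 8), CSMD3 (609 and 9), the protein phosphatase inhibitor gene PPP1R1B (239 and 4) and VAT1L (330 and 11), with edgeR adjusted p between 1.23e-09 and 0.000198. Of their MLL4KO counts, replicate 1 held all 11 of VAT1L, 7 of the 8 of COL4A5, 4 of the 6 of SFTA1P, 3 of the 4 of PPP1R1B and 4 of the 9 of CSMD3. It also held the 2 of PKIA and 1 of the 3 of PRICKLE2, so the sizes of these falls are uncertain. LRP12, PKIA and CSMD3 lie in a stretch of chromosome 8 in which most genes were lower. With the same limit of 5 CPM, the largest rise was that of UBB, a polyubiquitin gene (chromosome 17, 16380798 to 16382745), 8.34-fold from 15 ± 1.38 to 127 ± 4.73 CPM (log2 3.06 ± 0.07, edgeR adjusted p = 3.10e-11). LTN1, a ubiquitin ligase of ribosome quality control on chromosome 21, rose 6.18-fold from 12.7 ± 1.4 to 80.7 ± 4.69 CPM (edgeR adjusted p = 6.18e-10). The next largest rises under that limit were those of SYT11 (5.07-fold), the pacemaker channel gene HCN4 (5.06-fold), the sestrin gene SESN3 (4.95-fold), ARMH4 (4.80-fold), RASGEF1C (4.68-fold), the deubiquitinase gene OTUD7A (4.66-fold), FAM111A (4.64-fold) and ZNF469 (4.48-fold), with edgeR adjusted p between 1.23e-09 and 7.8e-05.

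**Figure D1:**
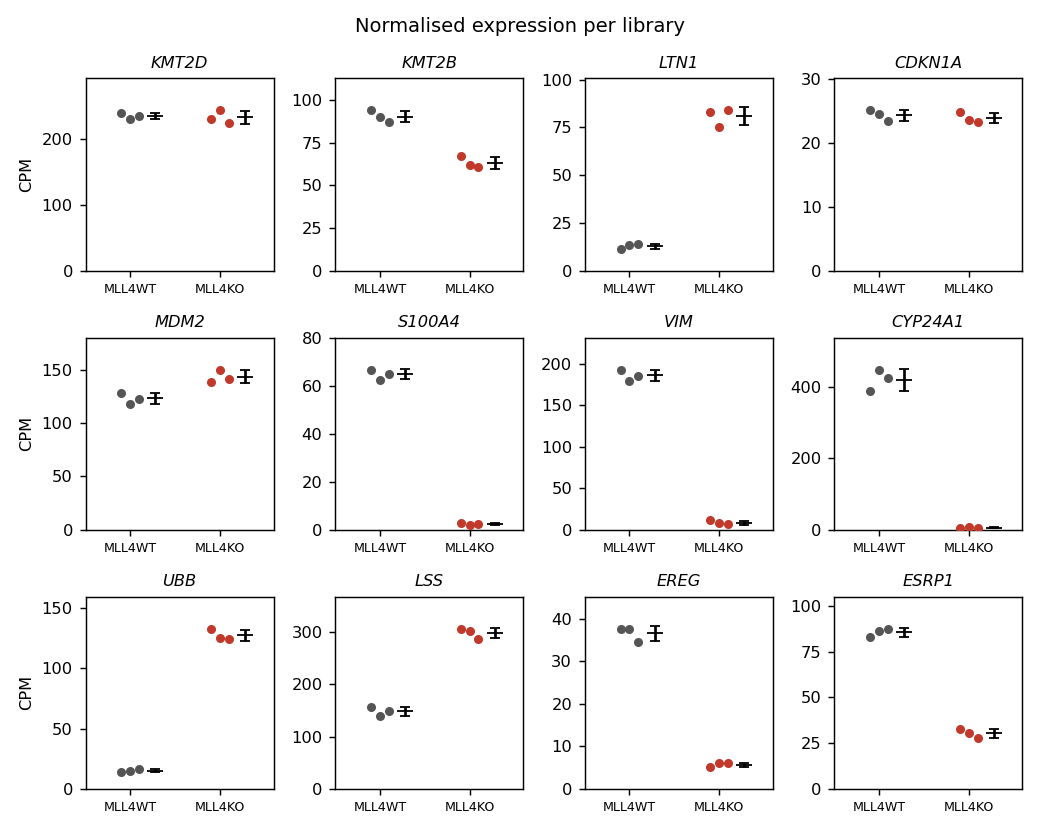
Normalised expression of 12 genes, in CPM on axes that start at 0. Points are the 3 libraries of MLL4WT (grey) and MLL4KO (red), and the bars give mean ± SD. KMT2D and CDKN1A overlap between the groups, S100A4, VIM and CYP24A1 are near 0 in all 3 MLL4KO libraries, and UBB is 8.34-fold higher there.

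By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 2885 genes rose and 3136 fell at an adjusted p under 0.05, or 6021 of 14543. Of these, 396 rose and 327 fell at least 2-fold, 54 rose and 130 fell at least 4-fold, and 7 rose and 72 fell at least 8-fold. Among genes at 5 CPM or more in the higher group, 1 rose and 24 fell at least 8-fold. The groups did not overlap in 52.5% of the tested genes, where chance gives 10%. The balance of directions depended on library scaling, since with total counts alone 3706 rose and 2394 fell, and with upper quartile factors 3561 rose and 2475 fell. Column names gave flow cell codes, with MLL4WT replicate 1 alone on its code. Within the 2 codes that held both genotypes, the differences had a Spearman correlation of 0.782 across genes, which are not independent replicates.

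**Figure D2:**
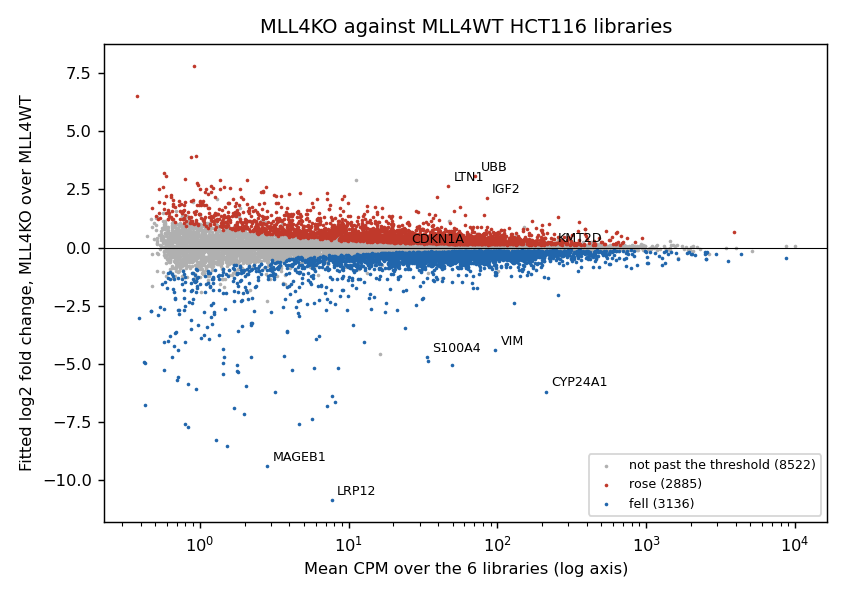
Fitted log2 fold change (MLL4KO over MLL4WT) of the 14543 tested genes against mean CPM over the 6 libraries on a log axis. Red points are the 2885 genes that rose and blue points the 3136 that fell; falls extend further from 0 than rises, and the values of LRP12 and MAGEB1, with 0 MLL4KO counts, depend on the prior count of the fit.

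p53-regulated transcription is named in the aim of the series, and the p53 target genes moved in both directions in these cells, for which the labels name no treatment. CDKN1A, a cell cycle inhibitor gene often used as a p53 readout (chromosome 6, 36676460 to 36687339), was at 24.3 ± 0.848 CPM in MLL4WT and 23.9 ± 0.834 CPM in MLL4KO (log2 -0.02 ± 0.07, edgeR adjusted p = 0.936). MDM2, which encodes the ubiquitin ligase of p53, rose 1.17-fold from 123 ± 5.13 to 143 ± 6.11 CPM (edgeR adjusted p = 0.00449), a call lost once GC and length trends were removed (log2 0.09, adjusted p = 0.184). KITLG, the KIT ligand gene, rose 1.6-fold from 487 ± 10.3 to 780 ± 30.7 CPM, CCNG1 rose 1.35-fold, CYFIP2 1.37-fold and the sestrin gene SESN1 1.86-fold (edgeR adjusted p between 4.42e-07 and 0.000181). EPHA2, an ephrin receptor gene, fell 2.21-fold from 231 ± 12.9 to 105 ± 1.49 CPM, the kinase gene PLK3 1.79-fold, TRAF4 1.39-fold and the growth arrest gene GADD45A 1.67-fold (edgeR adjusted p between 1.47e-08 and 1.24e-05).

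Of 67 measured p53 targets, 14 rose, 19 fell and 34 did not pass the test, or 15 and 19 adjusted over the list alone, with a median log2 fold change of -0.06. With total counts alone or upper quartile factors the balance turned, at 18 that rose and 16 that fell. The list was not set apart from the other genes by camera (adjusted p = 0.513, and 0.568 with an estimated correlation). The fry test, which asks whether the genes of a set moved on balance one way without comparing them with other genes, passed downward (adjusted p = 0.000886).

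The S100 genes, which encode small calcium-binding proteins of which the 12 measured lie on chromosome 1, fell together. S100A4 (chromosome 1, 153543613 to 153550136) fell 26.3-fold from 64.8 ± 2.10 to 2.42 ± 0.325 CPM (log2 -4.72 ± 0.10, edgeR adjusted p = 1.54e-11) and S100A6 fell 2.40-fold from 291 ± 1.90 to 121 ± 2.80 CPM (edgeR adjusted p = 1.23e-09). Of 12 measured members 9 fell, 8 of them at least 2-fold, none rose and 3 did not pass the test, with the same counts adjusted over the list alone. The median log2 fold change was -1.48, and camera set the list apart downward (adjusted p = 9.64e-27, and 0.0125 with an estimated correlation).

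Epithelial adhesion and keratin genes were mostly lower. ESRP1, an epithelial splicing regulator gene (chromosome 8, 94641074 to 94707466, within the lower stretch of chromosome 8), fell 2.82-fold from 85.5 ± 2.33 to 30.3 ± 2.58 CPM (edgeR adjusted p = 1.34e-08), and CLDN7, a tight junction claudin gene, fell 2.28-fold from 76.3 ± 3.58 to 33.3 ± 2.06 CPM (edgeR adjusted p = 6.70e-08). GRHL2, an epithelial transcription factor gene in the same stretch, rose 3.13-fold from a low level of 0.653 ± 0.211 to 2.03 ± 0.140 CPM, and the junction gene TJP3 rose 1.43-fold (edgeR adjusted p = 0.00162 and 0.00521). Of 31 measured members 18 fell, 3 rose and 10 did not pass the test, with 19 and 3 adjusted over the list alone. The median log2 fold change was -0.26 (camera adjusted p = 3.7e-08, and 0.0201 with an estimated correlation).

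Genes of mesenchymal cells split in direction, with the largest changes downward. VIM, the intermediate filament gene vimentin (chromosome 10, 17228259 to 17237593), fell 21.3-fold from 186 ± 6.82 to 8.54 ± 2.36 CPM (log2 -4.41 ± 0.13, edgeR adjusted p = 2.36e-08) and the myosin light chain gene MYL9 fell 1.77-fold (edgeR adjusted p = 1.95e-07). FN1, the fibronectin gene, rose 1.70-fold from 15.8 ± 1.24 to 26.6 ± 0.758 CPM and the matrix protease gene MMP14 rose 1.41-fold (edgeR adjusted p = 1.22e-05 and 0.000170). Of 20 measured members 8 fell, 5 rose and 7 did not pass the test, with 10 and 5 adjusted over the list alone, at a median log2 fold change of -0.13. The list passed camera downward (adjusted p = 0.000916) but not with an estimated correlation (adjusted p = 0.0846), on ranks (adjusted p = 0.612) or with limma-voom (adjusted p = 0.348), and its median turned to 0.10 with no filter and 0.12 with the DESeq2 Wald test, both over 32 members.

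**Figure D3:**
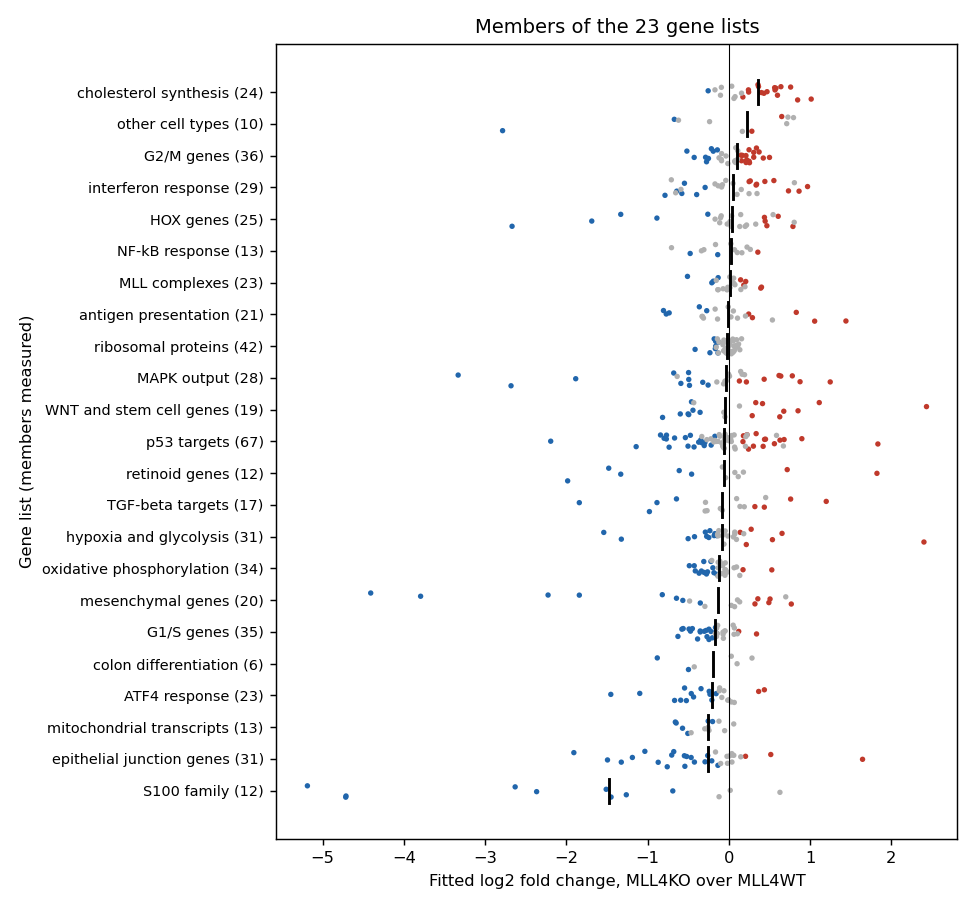
Fitted log2 fold change (MLL4KO over MLL4WT) of the measured members of the 23 gene lists, ordered by median. Red points rose, blue points fell, grey points did not pass the test, and black bars are medians, from -1.48 for the S100 family to 0.36 for cholesterol synthesis.

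Cholesterol synthesis genes rose together. LSS, the lanosterol synthase gene on chromosome 21, rose 2.02-fold from 149 ± 8.81 to 299 ± 9.77 CPM (edgeR adjusted p = 4.31e-08) and ACAT2, an acetyl-CoA acetyltransferase gene, rose 1.8-fold from 85.0 ± 7.58 to 154 ± 1.22 CPM (edgeR adjusted p = 6.58e-07). Of 24 measured members 16 rose, 1 fell and 7 did not pass the test, with the same counts adjusted over the list alone. The median log2 fold change was 0.36 (camera adjusted p = 1.61e-08, and 0.0201 with an estimated correlation).

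Replication genes of the G1/S transition were mostly lower by small amounts. RRM2, a ribonucleotide reductase subunit gene, fell 1.48-fold from 538 ± 18.0 to 364 ± 9.15 CPM (edgeR adjusted p = 1.68e-06) and ORC1, of the origin recognition complex, fell 1.55-fold (edgeR adjusted p = 3.01e-06). CHAF1B, a chromatin assembly gene on chromosome 21, rose 1.27-fold, and TYMS, the thymidylate synthase gene, rose 1.09-fold (edgeR adjusted p = 0.000245 and 0.0350); the TYMS call was lost with the replicate block (adjusted p = 0.0527), with no filter (adjusted p = 0.0617), without MLL4WT replicate 2 and without any 1 of the MLL4KO replicates (log2 between 0.12 and 0.14). Of 35 measured members 19 fell, 2 rose and 14 did not pass the test, with 24 and 3 adjusted over the list alone, at a median of -0.17. The list passed camera (adjusted p = 0.000916) but not with an estimated correlation (adjusted p = 0.28).

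Of 36 mitotic G2/M genes, 16 rose, 8 fell and 12 did not pass the test, the same adjusted over the list alone, and the list did not pass camera (median 0.09, adjusted p = 0.491). ASPM, a spindle pole gene, rose 1.41-fold and ECT2, a cytokinesis regulator gene, rose 1.24-fold, while CCNA2, the cyclin A2 gene, fell 1.35-fold and the mitotic transcription factor gene FOXM1 fell 1.22-fold (edgeR adjusted p between 2.14e-05 and 0.00018).

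ATF4-regulated amino acid and stress genes were mostly lower. SLC7A11, the cystine transporter gene, fell 2.74-fold from 54.8 ± 4.42 to 20.1 ± 0.934 CPM (edgeR adjusted p = 4.86e-08) and its partner subunit SLC3A2 fell 1.35-fold from 296 ± 8.75 to 218 ± 1.63 CPM (edgeR adjusted p = 8.80e-06). PHGDH, of serine synthesis, rose 1.29-fold and the chaperone gene DNAJB9 rose 1.35-fold (edgeR adjusted p = 0.000443 and 0.00890). Of 23 measured members 13 fell, 2 rose and 8 did not pass the test, with 14 and 2 adjusted over the list alone, at a median of -0.21 (camera adjusted p = 0.00628). The call was lost with an estimated correlation (adjusted p = 0.138), although the estimate, 0.00504, lay under the preset 0.01.

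Transcripts that follow ERK activity went both ways. EREG, an EGF receptor ligand gene, fell 6.42-fold from 36.6 ± 1.78 to 5.71 ± 0.466 CPM and the feedback inhibitor gene SPRY2 fell 3.70-fold (edgeR adjusted p = 1.14e-09 and 3.77e-09). SPRY4, of the same Sprouty family, rose 1.72-fold from 109 ± 4.86 to 188 ± 2.15 CPM and the ERK phosphatase gene DUSP6 rose 1.56-fold (edgeR adjusted p = 2.14e-07 and 2.05e-05). Of 28 measured members 10 fell, 8 rose and 10 did not pass the test, with 11 and 9 adjusted over the list alone, at a median of -0.04. The list passed camera downward (adjusted p = 0.00898) but not with an estimated correlation (adjusted p = 0.28), on ranks (adjusted p = 0.713) or with limma-voom (adjusted p = 0.484).

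Nuclear genes of oxidative phosphorylation were lower in 13 of 34 measured members and higher in 2, the same adjusted over the list alone, at a median of -0.12. NDUFV1, of complex I, fell 1.34-fold and SDHB, of complex II, fell 1.26-fold (edgeR adjusted p = 2.85e-05 and 9.07e-05). ATP5PO, an ATP synthase gene on chromosome 21, rose from 132 ± 4.84 to 191 ± 6.68 CPM (edgeR adjusted p = 5.57e-06), and NDUFA2 rose 1.13-fold (edgeR adjusted p = 0.0273), a call lost without MLL4WT replicate 2, MLL4KO replicate 1 or MLL4KO replicate 2, with the DESeq2 Wald test and at the depth of the shallowest library (log2 between 0.16 and 0.21). The list missed the camera threshold (adjusted p = 0.0598) and passed it without MLL4WT replicate 1 (adjusted p = 0.00561), where 21 members fell, but was far from it with an estimated correlation (adjusted p = 0.568). Of 13 mitochondrially encoded messenger transcripts 6 fell and none rose, the same adjusted over the list alone, at a median of -0.26. MT-CO1 fell 1.49-fold from 4240 ± 287 to 2853 ± 291 CPM and MT-CO2 fell 1.58-fold (edgeR adjusted p = 0.000140 and 0.000101). This list also missed the threshold (camera adjusted p = 0.0864, and 0.854 with an estimated correlation of 0.639 between its genes) and passed it without MLL4WT replicate 2 (adjusted p = 0.00386) and without MLL4KO replicate 1 (adjusted p = 0.00617), while 3 members fell without MLL4WT replicate 1.

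Of 42 ribosomal protein genes 8 fell and none rose, or 4 and none adjusted over the list alone, at a median of -0.03 (camera adjusted p = 0.815). RPL7, in the lower stretch of chromosome 8, fell 1.33-fold and RPS12 fell 1.12-fold (edgeR adjusted p = 0.00458 and 0.0104). The RPS12 call was lost with total counts alone, with upper quartile factors, with GC and length trends removed, and without MLL4WT replicate 3, MLL4KO replicate 1 or MLL4KO replicate 2 (log2 between -0.16 and -0.04). Scaling turned the direction of this family, with 9 members that rose and 1 that fell with total counts alone and 5 and 1 with upper quartile factors, and 17 fell and 6 rose without MLL4WT replicate 1.

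WNT target and intestinal stem cell genes went both ways, with 8 of 19 higher and 7 lower, the same adjusted over the list alone. TNFRSF19, a receptor gene of the TNF family, rose 5.40-fold from 0.897 ± 0.402 to 4.44 ± 0.0562 CPM and the transcription factor gene TCF7L2 rose 1.33-fold, while CD44 fell 1.51-fold and CCND1, the cyclin D1 gene, fell 1.41-fold from 835 ± 36.6 to 593 ± 3.71 CPM (edgeR adjusted p between 1.4e-06 and 3.27e-05). The median was -0.05, the mean 0.14 and the direction of the test downward (camera adjusted p = 0.8). Of the colon differentiation genes only 6 were measured, and KLF5, an epithelial transcription factor gene, fell 1.84-fold and CA2, a carbonic anhydrase gene in the lower stretch of chromosome 8, fell 1.41-fold (edgeR adjusted p = 2.71e-06 and 2.68e-05). These were the 2 members that fell, also adjusted over the list alone, none rose, and the list did not pass camera (median -0.20, adjusted p = 0.157).

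Of 25 measured HOX genes, which pattern the body axis, 5 rose and 5 fell, the same adjusted over the list alone. HOXA3 fell 6.36-fold from 17.0 ± 1.81 to 2.62 ± 0.261 CPM and its neighbour HOXA4 fell 3.22-fold, while HOXB9 rose 1.73-fold and HOXB13 rose 1.36-fold (edgeR adjusted p between 4.08e-08 and 0.000354). The median was 0.03 and the mean -0.09 (camera downward, adjusted p = 0.999). Of 12 retinoid genes 2 rose and 5 fell, or 3 and 5 adjusted over the list alone, with TGM2, a transglutaminase gene, up 3.54-fold, the retinol uptake receptor gene STRA6 down 3.96-fold and RDH10, a retinol dehydrogenase gene in the lower stretch of chromosome 8, down 1.53-fold (edgeR adjusted p between 1.2e-06 and 1.93e-05). The retinoid list did not pass camera (median -0.06, adjusted p = 0.814).

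Interferon-stimulated genes also split, with 9 of 29 higher and 6 lower, the same adjusted over the list alone (median 0.05, camera adjusted p = 0.815). STAT2, an interferon signal transducer gene, rose 1.47-fold and the antiviral gene IFIT1 rose 1.96-fold, whereas IFITM3, an inhibitor of virus entry, fell 1.73-fold from 193 ± 22 to 111 ± 5.05 CPM and its near-identical neighbour IFITM2 fell 1.56-fold (edgeR adjusted p between 1.08e-05 and 0.000768). Of 21 antigen presentation genes 5 rose and 5 fell, or 6 and 6 adjusted over the list alone. HLA-B rose 1.18-fold and HLA-DMB rose 2.71-fold from 1.03 ± 0.273 to 2.67 ± 0.385 CPM, while the immunoproteasome gene PSMB10 fell 1.71-fold and B2M, the light chain of MHC class I, fell 1.29-fold (edgeR adjusted p between 1.24e-05 and 0.00143). Reads can be shared among IFITM genes and among HLA genes, so these values are uncertain. The median was -0.01 and the mean 0.03 (camera downward, adjusted p = 0.861). Of 13 NF-kB response genes NFKBIE, an inhibitor of NF-kB, rose 1.28-fold and the NF-kB subunit gene NFKB2 fell 1.39-fold (edgeR adjusted p = 0.00405 and 5.40e-05). NFKB1 also passed (log2 -0.14 ± 0.05, edgeR adjusted p = 0.0469) and lost its call when adjusted over the list alone and under 15 of 18 other settings, leaving 1 and 1, and the list did not pass camera (median 0.02, mean -0.07, test upward, adjusted p = 0.999).

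Of 17 TGF-beta and BMP targets 4 rose and 4 fell, or 5 and 4 adjusted over the list alone (median -0.08, camera adjusted p = 0.815), and 6 rose with total counts alone. The receptor gene TGFBR1 rose from 50.7 ± 0.642 to 63.3 ± 1.89 CPM and BMPR2 rose 1.35-fold, while CCN2, a matricellular protein gene, fell 3.58-fold from 14.3 ± 1.15 to 4.01 ± 0.327 CPM and the BMP target ID1 fell 1.85-fold (edgeR adjusted p between 4.72e-07 and 0.000993). Of 31 hypoxia and glycolysis genes 6 rose and 11 fell, or 6 and 12 adjusted over the list alone (median -0.08, mean -0.05, camera adjusted p = 0.815), and 9 rose and 9 fell with total counts alone. NDRG1 rose 1.57-fold and the phosphofructokinase gene PFKL, on chromosome 21, rose 1.45-fold, while its platelet-type relative PFKP fell 1.42-fold and the glucose transporter gene SLC2A3 fell 2.91-fold (edgeR adjusted p between 2.91e-06 and 1.09e-05).

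Markers of fibroblasts, leukocytes, endothelium and neurons were mostly too low to test, with 10 of 24 measured. COL3A1, a fibroblast collagen gene, fell 6.90-fold from 5.22 ± 0.288 to 0.776 ± 0.367 CPM and the tubulin gene TUBB3 fell 1.59-fold from 219 ± 12.1 to 137 ± 3.99 CPM (edgeR adjusted p = 1.57e-05 and 1.26e-06). COL1A1 rose 1.22-fold and PDGFRB rose 1.57-fold (edgeR adjusted p = 0.0106 and 0.0229), and both calls were lost with the DESeq2 Wald test (adjusted p = 0.054 and 0.0869). PDGFRB also lost its call at the depth of the shallowest library (log2 0.47, adjusted p = 0.218), without MLL4KO replicate 1 (log2 0.63, adjusted p = 0.0798) and without MLL4KO replicate 2 (log2 0.65, adjusted p = 0.0712). Adjusted over the list alone, 4 rose and 2 fell, and the list did not pass camera (median 0.22, mean -0.10, test downward, adjusted p = 0.815).

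Along the genome, 2 regions moved furthest. Genes of chromosome 21 were higher in MLL4KO, with 100 of 147 tested genes past the threshold upward and 3 downward, and a median log2 fold change of 0.51 (quartiles 0.31 and 0.78). Genes between 70573442 and 113437099 on chromosome 8 were lower, with 80 of 123 past the threshold downward and 6 upward, and a median of -0.49 (quartiles -0.69 and -0.26). The 362 tested genes on the rest of chromosome 8 had a median of -0.02. Each MLL4KO library gave similar medians against the MLL4WT mean, 0.47, 0.50 and 0.49 on chromosome 21 and -0.48, -0.45 and -0.46 in the chromosome 8 segment. In windows of 100 neighbouring genes the highest median was 0.57 on chromosome 21 and the lowest -0.50 on chromosome 8, where 100 shuffles of gene order gave medians between -0.16 and 0.18. The most extreme windows of chromosomes 1, X, 11 and 17 also lay past that range, by far less (-0.19, 0.19, -0.19 and -0.18). RUNX1, a transcription factor gene of chromosome 21 chosen after its values were seen, rose 3.01-fold from 25.7 ± 2.48 to 75.9 ± 1.85 CPM (edgeR adjusted p = 1.15e-08).

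**Figure D4:**
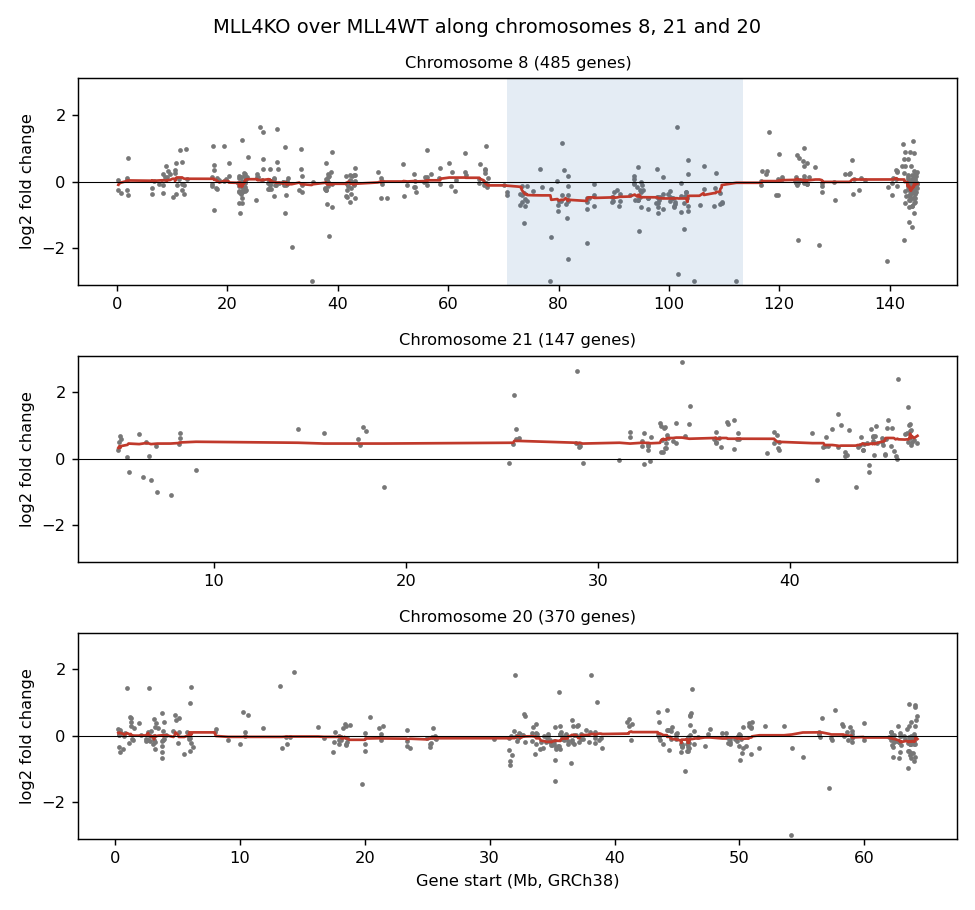
Fitted log2 fold change (MLL4KO over MLL4WT) of tested genes by start position in Mb on chromosomes 8, 21 and 20, with values beyond 3 in size drawn at 3. Red lines are running medians and the shaded part is the chromosome 8 segment of 123 genes with a median of -0.49; chromosome 21 has a median of 0.51, and chromosome 20 is drawn for comparison.

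Several statements rest on small differences, and 12 of the 23 lists had a median that changed sign under another setting. The medians of the p53, MAPK, WNT, retinoid, antigen presentation and ribosomal protein lists, between -0.06 and -0.01, changed sign with total counts alone (0.01, 0.02, 0.01, 0.00, 0.05 and 0.04), where the median of all genes moved to 0.06, and those of the MAPK, WNT, antigen presentation and ribosomal protein lists also did so with upper quartile factors. With GC and length trends removed, those of the WNT, retinoid, antigen presentation, ribosomal protein, MLL complex, NF-kB and TGF-beta lists changed sign, with no filter those of the mesenchymal, interferon, NF-kB and antigen presentation lists, and with the DESeq2 Wald test the first 3 of these. The TGF-beta median also turned with a flow cell term (0.002) and without MLL4WT replicates 1 or 3 (0.006 and 0.08), the colon differentiation median without the 2 regions (0.04), and those of the MAPK, interferon, antigen presentation and ribosomal protein lists without 1 library. Camera at the preset correlation passed 7 lists in the real grouping of the libraries. It passed between 0 and 6, mostly at least 3, when libraries were regrouped across genotypes. Those groupings were unbalanced and kept part of the genotype difference, so they give no rate of false list calls. Calls at the preset correlation alone count for less, since only 3 lists also passed with an estimated correlation. A higher correlation does not account for the loss of the mesenchymal and ATF4 calls. Their estimates, -0.0384 and 0.00504, lay under the preset 0.01. Among 120 genes, those named by the fixed rule with the S100 members, 28 shared annotated exon bases with another tested gene, mostly on the opposite strand. DUSP6, TYMS and PSMB10 shared at least 25% of theirs, and since no source used here says that strand was kept, their values are uncertain.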

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

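The tests with a flow cell term, with thinning, with GC and length trends removed and without chromosome 21 and the chromosome 8 segment were chosen only after the data were seen. Under the 18 settings the changed genes numbered between 4479 and 7455, 2090 to 3706 rose and 2316 to 3986 fell, each within 1.5 times the main count, and every main call that a setting kept had the same direction. The lowest share of main calls kept was 73.2%, without MLL4KO replicate 2, and the highest 98.8%, with size factors of the DESeq2 kind. Genes that fell at least 2-fold numbered 500 in place of 327 with no filter, where 27126 genes were tested. Of 1967 values under other settings of the 110 genes named by the fixed rule, 40 lost their call. All 40 were of NFKB1, TYMS, RPS12, NDUFA2, PDGFRB, COL1A1, CXXC1 and MDM2. Most of the 110 genes were picked for a large fold or a small adjusted p, and uncalled ones cannot lose a call. The low loss therefore does not stand for all called genes. None of these genes that was called in the main test changed direction, and sign changes of uncalled genes were not counted. With every library thinned to 6829400 counts, 4749 of 13183 tested genes were called.

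The S100, epithelial junction and cholesterol synthesis lists passed under every setting run on them. With an estimated correlation the G1/S (adjusted p = 0.28), mesenchymal (0.0846), MAPK (0.28) and ATF4 (0.138) lists did not. The estimates were 0.0762, -0.0384, 0.0368 and 0.00504 in that order. Those of the mesenchymal and ATF4 lists lay under the preset 0.01, so a higher correlation did not cost these lists their call. The mesenchymal and MAPK lists also missed the threshold with camera on ranks (0.612 and 0.713) and with limma-voom (0.348 and 0.484). Oxidative phosphorylation, at 0.0598 in the main test and 0.568 with an estimated correlation, passed on ranks (0.00428), with fry (0.00373), no filter (0.00756), limma-voom (0.00392), a flow cell term (0.00592) and without the 2 regions (0.038), and ranged from 0.00561 to 0.119 as single libraries were left out. Mitochondrial transcripts, at 0.0864 in the main test, 0.854 with an estimated correlation and 0.07 with fry, passed on ranks (0.0214), with no filter (0.00756), limma-voom (0.0164), a flow cell term (0.00048) and thinning (0.046), and ranged from 0.00386 to 0.579 without single libraries. By fry, which does not compare a list with other genes, the p53 (0.000886), colon differentiation (0.00606), retinoid (0.032), antigen presentation (0.032), TGF-beta (0.00257), hypoxia (0.00148) and other cell type (0.0442) lists also passed. The cause of these differences was not tested.

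No pairing by replicate number was seen: deviations from the group means of the libraries numbered 1, 2 and 3 correlated at 0.0217, 0.0278 and 0.00951. Pairs of the 2 genotypes with different numbers gave between -0.0584 and 0.0296, and the libraries numbered 2 also shared a flow cell code. Such small values do not show whether the cultures were paired. With the replicate block 5713 genes changed, and mitochondrial transcripts passed the list test (adjusted p = 0.00118).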

Other observations

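The tests of flow cell codes, of GC and length trends, of lists without the 2 chromosome regions, and of the share of genes that moved in each region were chosen only after the result was seen, as were the genes named next. Among the 24 genes at 5 CPM or more that fell at least 8-fold, the gap junction gene GJA1 fell 29.5-fold (65.8 ± 3.86 to 2.19 ± 0.315 CPM), the drug efflux transporter gene ABCC2 33.0-fold (96.5 ± 7.71 to 2.94 ± 0.346 CPM), the interleukin 7 receptor gene IL7R 35.7-fold (16.6 ± 3.37 to 0.481 ± 0.164 CPM) and the sodium channel gene SCNN1A 11.1-fold (43.7 ± 4.23 to 3.86 ± 0.199 CPM), with edgeR adjusted p between 1.54e-11 and 1.65e-08. COL4A6, the head-to-head neighbour of COL4A5 on chromosome X, went from 4 ± 1.08 to 0.0649 ± 0.0665 CPM with it (edgeR adjusted p = 3.06e-06). IGF2, the insulin-like growth factor gene, rose 4.33-fold from 32.2 ± 3.24 to 137 ± 2.47 CPM (edgeR adjusted p = 5.66e-10).

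MT-RNR1, the small mitochondrial ribosomal RNA, rose 1.58-fold from 3037 ± 190 to 4803 ± 286 CPM (edgeR adjusted p = 4.14e-06), MT-RNR2 had a log2 fold change of 0.09 ± 0.06 (edgeR adjusted p = 0.272), and MT-CO1 fell 1.49-fold. KDM6A, the demethylase subunit of the MLL4 complex, fell 1.14-fold (34.4 ± 0.356 to 30.1 ± 0.309 CPM, edgeR adjusted p = 0.0254).

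The number of changed genes was weighed against chance, depth and sequencing run. Only 10 splits of the 6 libraries exist, too few for a share under 0.05. The real split gave 6021 changed genes, 723 changed at least 2-fold and 7 lists. It was the 1 split with a result as large for each, while the highest of the others gave 1, 1 and 6. Each of the others mixed the genotypes, which puts any genotype difference inside both groups, so these counts are not a chance level. Had the low depth of MLL4WT replicate 1 made the calls, their number would have dropped without it, and 7343 genes changed without that library. The sequencing run is argued against by the Spearman correlation of 0.782 across genes between differences within 2 flow cell codes. Loss of MLL4 and any other difference between the MLL4WT and MLL4KO cultures, such as separate cloning, stay open and untested.

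Higher expression across chromosome 21 and lower expression across part of chromosome 8 may reflect a copy number difference between the cultures, a hypothesis whose prediction was met by the highest window median, 0.57 on chromosome 21, where the whole chromosome had 0.51, under the log2 ratio of 0.58 for 3 copies against 2. A few strongly changed genes do not account for the rise of chromosome 21, since 88.4% of its genes were higher. In the chromosome 8 segment 87.8% were lower, which decides nothing there, since its ends were set by its values. A change in expression over whole regions without a change of copies stays open, since genomic DNA was not analysed here. LTN1, LRP12, PKIA and CSMD3 changed far more than their regions did.

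Among the 7 lists that passed the threshold, a regional change at 1q21 as the whole cause for the S100 genes is argued against by the 46 other tested genes within 1 Mb, with a median log2 fold change of -0.075 (quartiles -0.24 and 0.10) against -1.48 for the S100 genes. A small regional fall stays open, since 16 of these neighbours fell and 4 rose. The most extreme window of chromosome 1, from 151873584 to 156644887, holds the S100 genes. Its median of -0.19 lay under the lowest of the shuffles (-0.16). Log2 fold changes had a Spearman correlation across genes of 0.21 with transcript length and -0.17 with GC content. Their median was 0.07 in the lowest GC quartile and -0.10 in the highest, so changes of that size are uncertain. With these trends removed, 81.2% of the main calls were kept. Then 7 lists kept their call and direction, and 7 did so without the genes of chromosome 21 and the chromosome 8 segment. Leaving out those regions could change little and decides little. The S100, mesenchymal, MAPK and ATF4 lists had 0 measured members there, cholesterol synthesis 1, and the G1/S and epithelial junction lists 2 each. Whether the lists follow the loss of MLL4 or another difference between the cultures stays open and untested. Of these lists 4 lost their call with an estimated correlation, and most other groupings of the libraries passed between 3 and 6 lists. Those groupings mixed the genotypes and kept part of their difference, so they give no rate of false list calls.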
